A study of Homo sapiens with 20 samples.

How the data were processed

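The data are expression values from 20 arrays of MM134 breast cancer cells, 4 in each of 5 groups. The groups are baseline at 0 h, vehicle at 3 and 24 h, and 1 nM E2 at 3 and 24 h, all after 3 days of hormone deprivation. Total RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix U133 A 2.0 arrays, per the labels' protocols. The arrays of the E2 group at 24 h have a treatment entry that reads baseline, while their titles and descriptions say E2. The titles were followed.

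The deposited values are on the log2 scale and were made with RMA in the affy package, per the submitters' processing notes, with versions not given in the sources used here. RMA corrects the background, quantile-normalises all arrays together and summarises the probes of a probe set. It makes the distribution of values nearly equal in all arrays, so a change shared by most genes cannot be seen, and it tends to compress fold changes of dim genes. The deposited values ran from 2.24 to 14.4, and array medians from 7.37 to 7.41. RMA values carry no detection call, so no gene was called absent, and log2 levels were not compared between genes. The number of arrays limits the precision.

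The value table held 22277 probe sets, of which 62 were AFFX controls and were left out of the gene tests. Of the others, 19064 probe sets had 1 gene symbol by the platform's annotation, 1043 had several and 2108 had none. Gene identifiers of 19052 were found in a RefSeq gene table, which changed 0 symbols. Only probe sets with 1 symbol were named. For each gene the probe set with the highest mean over all 20 arrays stood for the gene, giving 11963 genes, of which 4310 had several probe sets. Genes with no such probe set were not analysed here.

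Differences were tested in R 4.3.3 with limma 3.58.1. A linear model with the 5 groups was fitted to all 20 arrays, so that the groups share an estimate of the spread with 15 residual degrees of freedom, followed by eBayes with a trend of variance on mean level. The comparisons were E2 against vehicle at 3 h and at 24 h, the difference of these effects, and vehicle against baseline at each time. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes of a comparison, and genes under 0.05 were called. Vehicle groups serve in both an E2 and a baseline comparison, so their chance deviations enter both with opposite sign, and no overlap between such comparisons was counted.

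The 24 gene lists were tested with limma's camera, with an inter-gene correlation preset at 0.01, adjusted over the lists. Lists needed at least 5 measured genes. Some genes belong to several lists, so the lists are not independent. Each list was also tested with the correlation estimated from the data, and with fry. Counts of members adjusted over the list alone use Benjamini-Hochberg within the list. Means of a list per array were compared with exact permutation tests, two-sided, over 70 arrangements of 8 arrays.

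The genes named were fixed by a rule. It takes the 10 largest rises and 10 largest falls of each E2 comparison, among genes under the adjusted p threshold whose 4 arrays of a group all lay on the same side of the other group's. It takes the 5 largest each way of the other comparisons, up to 4 members of each list with the smallest p, and always ESR1, PGR, GREB1, TFF1, MYC, CCND1, FGFR1, WNT4, SNAI1 and CDH1. A few list members named beyond it were chosen after their values were seen. Groups, comparisons, lists, this rule and the alternatives, other than the RNA quality covariate, were chosen before the data were examined.

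The test was checked on simulated data with 11963 genes for the comparison at 3 h. It recovered 44% of 50 genes changed by 1.1-fold, 76% at 1.25-fold and 100% at 1.5-fold and at 2-fold, and called 0.085% of 11763 unchanged genes. Far fewer genes were changed in the simulation than were called in the data, and its noise was independent between genes. These rates therefore do not carry over to the real comparisons. The labels describe the 4 arrays of a group as biological replicates and give them the letters A to D, without saying that a letter marks a shared culture or day.

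Alternatives were a fit with the letter as a block, fits of the compared groups alone, eBayes without the trend, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, all probe sets each tested, cyclic loess or quantile normalization of the deposited values, array weights, a minimum change of 1.5-fold, a threshold of 0.01, the baseline arrays as control, and leaving out each array. A fit with the 3 prime minus 5 prime difference of the ACTB and GAPDH control probe sets as a covariate was added after seeing the data. Plots were drawn with matplotlib.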

Results

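Gene expression was measured in MM134 cells (also written MDA-MB-134-VI), an established human breast cancer line derived from an invasive lobular carcinoma that carries the estrogen receptor. The cells were kept for 3 days in medium with charcoal-stripped serum, which removes steroid hormones. They then received 1 nM estradiol (E2), the main natural estrogen, or the vehicle, 0.01% ethanol, for 3 or 24 h. Cells taken at 0 h, after deprivation and before treatment, formed a baseline group. Each of the 5 groups held 4 arrays, described as biological replicates, giving 20 Affymetrix U133 A 2.0 arrays. The comparisons address how cells of a lobular carcinoma respond to estrogen. Array medians lay between 7.37 and 7.41 on the log2 scale, and the number of arrays per group limits the precision. Values of 11963 genes were compared with limma, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Replicate arrays of a group correlated across genes at r of 0.998 to 0.999, where genes are not independent replicates. The first principal component, with 44.5% of the variance, set the E2 arrays apart from the vehicle and baseline arrays.

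**Figure D1:**
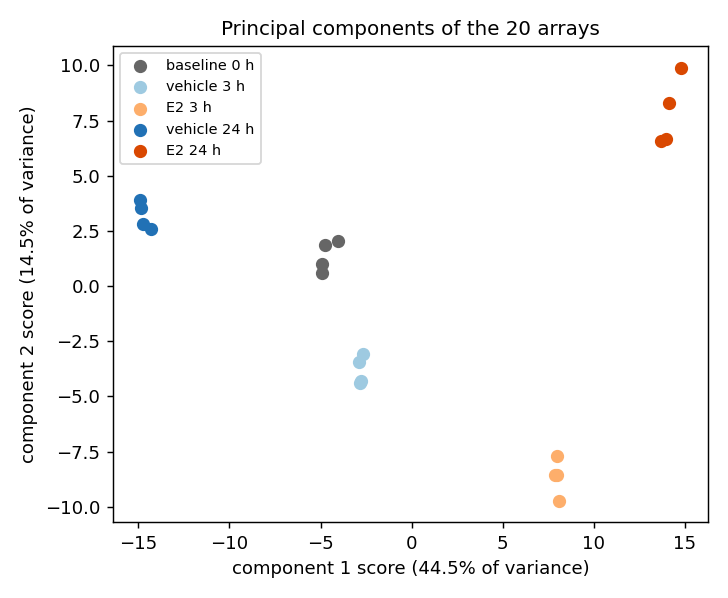
Scores of the 20 arrays (points, coloured by group) on the first and second principal components of the gene values, with the percent of variance on each axis. The E2 arrays at 24 h lie at 13.7 or above on component 1 and the vehicle arrays at 24 h at -14.3 or below, with the other groups between them.

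E2 raised a small set of genes strongly within 3 h. RASGRP1, an activator of RAS proteins, was 7.80-fold higher than in vehicle (log2 change 2.96 ± 0.063 SE, n = 4 arrays per group, limma adjusted p = 1.90e-24). STC2, a secreted glycoprotein, rose 4.21-fold, the nuclear receptor gene NR5A2 3.66-fold, the somatostatin receptor gene SSTR2 3.34-fold and MYC, a transcription factor that drives growth, 3.27-fold. PTGES rose 3.23-fold, JAK2 3.02-fold, FCGR2B 2.92-fold, EGR3 2.90-fold and MYB 2.60-fold. The largest fall was in AMIGO2, a cell adhesion gene, at 2.38-fold lower (log2 change -1.25 ± 0.041 SE, limma adjusted p = 6.18e-20).

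PDE4B, a cyclic AMP phosphodiesterase, was 2.22-fold lower at 3 h, RND3 2.21-fold lower, CDC42EP3 2.06-fold lower and RNF43, which limits WNT receptors, 1.87-fold lower. FLRT3 fell to 1.82-fold lower, BMP4 to 1.80-fold, FBN2 to 1.75-fold, GCNT1 to 1.71-fold and RND1 to 1.69-fold. The naming rule required that in each of these 20 genes the 4 E2 arrays all lay on the same side of the 4 vehicle arrays. In all, 1710 of the 11963 genes were called at 3 h by limma, 834 higher and 876 lower with E2. Most changes were small, with a median of 1.14-fold. At least 1.5-fold changes were found in 142 genes, 108 higher and 34 lower.

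Classic estrogen-induced genes rose together at 3 h. Of 39 measured members 32 rose and none fell (34 rose when adjusted over the list alone), and the list was called upward (camera adjusted p = 4.97e-70, and 2.26e-09 with an estimated correlation). Among them GREB1, an estrogen receptor cofactor, rose 2.22-fold and TFF1, a secreted trefoil peptide, 2.19-fold. PGR, the progesterone receptor gene, lay at 3.45 ± 0.08 (SD, n = 4) in E2 arrays and 3.46 ± 0.13 in vehicle arrays and was not called (limma adjusted p = 0.955). These PGR values lie near the low end of the deposited range (2.24 to 14.4). A lack of response thus cannot be told from a lack of detection. Of 12 estrogen-repressed genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with CCNG2 1.51-fold, SMAD6 1.51-fold, TGFB3 1.40-fold and EFNA1 1.29-fold lower. That list was called downward (camera adjusted p = 1.50e-04, and 0.0132 with an estimated correlation).

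Ribosome biogenesis genes were the other large group. 18 of 31 rose and none fell at 3 h (19 adjusted over the list alone), including NOP16 (1.49-fold), NIP7 (1.38-fold) and POLR1C (1.37-fold), with a camera adjusted p of 8.68e-17, and 0.00101 with an estimated correlation. Immediate early and growth factor response genes went both ways, 9 of 30 higher and 5 lower (10 and 6 adjusted over the list alone). MYC and EGR3 led the rises, while JUN was 1.34-fold and DUSP6, a phosphatase that damps MAP kinase signalling, 1.43-fold lower. The immediate early list was called upward (camera adjusted p = 0.00477), with adjusted p = 0.0683 with an estimated correlation. Its mean was 0.157 on the log2 scale and its median 0.055. MYC and EGR3 also belong to the estrogen-induced list, and whether the list would be called without them was not tested. The mitosis list was called downward at 3 h (camera adjusted p = 0.0323), with adjusted p = 0.641 with an estimated correlation. Only NUSAP1, a spindle gene, fell among its 41 members, at 1.05-fold lower, and 0 fell when adjusted over the list alone. DNA replication and S phase genes rose in 3 of 42 cases and fell in 3 (camera adjusted p = 0.985), cell cycle inhibitors rose in 4 of 18 and fell in 6 (0.187), and cholesterol synthesis genes rose in 2 of 18 and fell in 3 (0.174). Adjusted over the list alone, 7 inhibitors and 7 cholesterol synthesis genes fell. None of 10 housekeeping genes was called (0.796).

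Genes chosen for lobular carcinoma and for FGF and WNT signalling changed one by one rather than as lists. WNT4, a secreted WNT ligand, rose 2.10-fold at 3 h and the WNT receptor gene FZD7 2.48-fold, while FZD2 (1.30-fold) and TCF7L2 (1.19-fold) were lower. SNAI1, a repressor of epithelial genes, rose 1.58-fold, and TWIST1, another such factor, was 1.65-fold lower. CDH1, which encodes E-cadherin, changed by -0.14 on the log2 scale (limma adjusted p = 0.0164), a call lost without replicate A of the E2 or of the vehicle group (adjusted p of 0.0702 and 0.0738) and with the mean of its probe sets (0.103). CCND1 rose 1.19-fold. FGFR1 differed by 0.08 ± 0.029 (SE) on the log2 scale and was not called (limma adjusted p = 0.0756), though it was with the compared groups alone (0.00265) and with array weights (0.0145). FGFR3 rose 1.54-fold. Transcripts of ESR1, the estrogen receptor gene, rose 1.06-fold, a call that 1 of its 9 probe sets gave and that turned to -0.0257 on the log2 scale with their mean (adjusted p = 0.798). In the luminal factor list TFAP2C rose 1.69-fold and NRIP1 1.51-fold, and FOXA1 (1.23-fold) and TFAP2A (1.29-fold) were lower.

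The FGF signalling list had 1 of 14 genes higher and 1 lower (camera adjusted p = 0.602), and the WNT list 2 of 32 higher (3 over the list alone) and 7 lower (camera adjusted p = 0.486). In the adhesion list 4 of 24 rose and 8 fell (10 over the list alone; camera adjusted p = 0.214), and in the luminal factor list 5 of 19 rose and 5 fell (camera adjusted p = 0.940). Markers of fibroblasts, immune cells and endothelium had no member called at 3 h, and 1 of 7 basal markers, MYLK, was 1.12-fold lower (camera adjusted p from 0.796 to 0.985 over these lists). The 3 prime minus 5 prime difference of the ACTB and GAPDH control probe sets, a measure of RNA integrity, was 0.131 ± 0.034 (SD, n = 4) in E2 arrays and 0.091 ± 0.010 in vehicle arrays at 3 h. The highest vehicle array (0.101) lay below the lowest E2 array (0.113). With 5 lists called at 3 h, 4 of the 35 splits of the 8 arrays, the real one included, called as many, though mixed splits can retain part of the E2 effect. An exact permutation test of a list mean could not go below p = 0.0286, or 0.0557 after Benjamini-Hochberg adjustment over 144 such tests.

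At 24 h more genes differed between E2 and vehicle than at 3 h. PDZK1, a scaffold protein gene, was 19.4-fold higher with E2 than with vehicle (log2 change 4.28 ± 0.037 SE, n = 4 arrays per group, limma adjusted p = 2.45e-34). MPPED2 rose 5.33-fold, RASGRP1 4.62-fold, TFF1 4.61-fold, MGP, an inhibitor of calcification, 3.94-fold and STC2 3.82-fold. The largest fall was in DEPP1, a target of FOXO factors, at 6.20-fold lower (log2 change -2.63 ± 0.10 SE, limma adjusted p = 9.92e-19). FBN2 was 5.18-fold lower, MAP1B, a microtubule protein gene, 4.59-fold lower and PDE4B 3.85-fold lower.

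TFCP2L1 rose 3.76-fold, the ion channel gene ASIC2 3.59-fold, RGS5 3.53-fold and DAB2 3.40-fold. DDC, which encodes the enzyme that makes dopamine and serotonin, was 3.59-fold lower at 24 h, and TXNIP, which limits glucose uptake, 3.43-fold lower. The cholesterol exporter gene ABCA1 was 3.41-fold, TIMP3 3.34-fold, AMIGO2 3.25-fold and the interleukin 1 receptor gene IL1R1 3.11-fold lower. As at 3 h, the naming rule required that in each of these 20 genes the 4 E2 arrays lay on the same side of all 4 vehicle arrays. By limma 5441 genes were called at 24 h, 2686 higher and 2755 lower, with a median change of 1.17-fold. Of these, 508 changed by at least 1.5-fold, 245 higher and 263 lower. Against baseline the E2 arrays differed less between times, with 2844 genes called at 3 h and 4291 at 24 h. At least 1.5-fold changes from baseline were found in 157 and 221 genes. Part of the wider difference at 24 h thus lay in vehicle arrays that had moved from baseline.

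**Figure D2:**
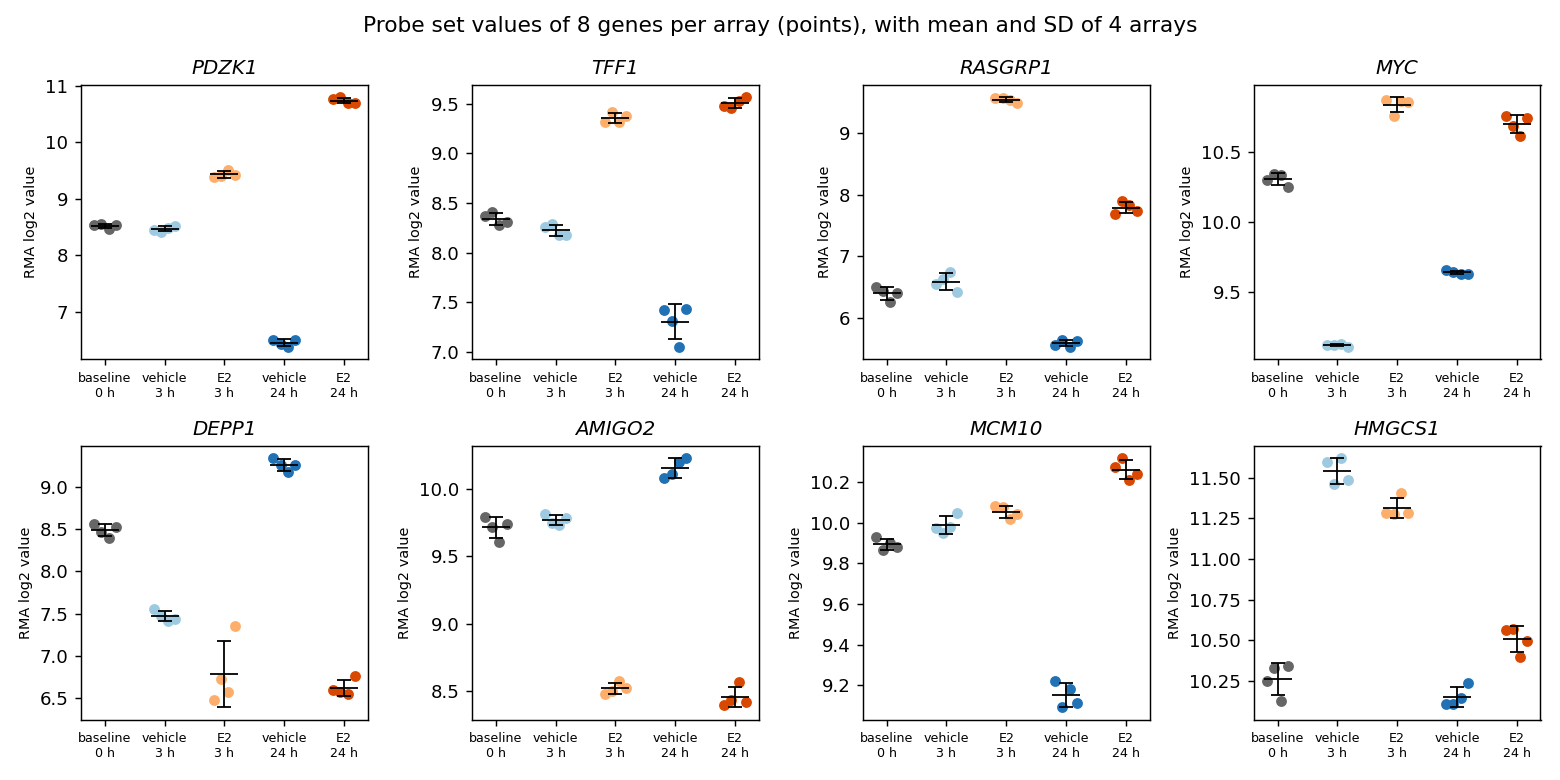
RMA log2 values of 8 genes, with a point per array, grouped by treatment and time; the black line and bars are the mean and SD of 4 arrays, and each panel has its own vertical scale. PDZK1 averages 6.46 in vehicle and 10.74 in E2 arrays at 24 h, and HMGCS1 averages 10.26 at baseline and 11.54 in vehicle arrays at 3 h.

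Nearly the whole DNA replication and S phase list was higher with E2 than with vehicle at 24 h. Of 42 genes 41 were higher and 1 lower (the same counts adjusted over the list alone), and the list mean was 0.53 higher on the log2 scale (camera adjusted p = 4.59e-27, and 1.61e-04 with an estimated correlation). MCM10, a replication initiation factor, rose 2.16-fold, the licensing factor gene CDC6 1.97-fold, the phosphatase gene CDC25A 1.73-fold and RRM2, a subunit of ribonucleotide reductase, 1.53-fold. Most of this difference was a lower level in vehicle arrays, whose list mean was -0.42 from baseline. In E2 arrays 23 of the 42 genes were higher than at baseline and 2 lower (camera adjusted p = 4.38e-06), with adjusted p = 0.0506 with an estimated correlation. In the mitosis list 28 of 41 rose and 1 fell (28 and 1 adjusted over the list alone), with AURKB 1.45-fold, MELK 1.43-fold, FOXM1 1.41-fold and MKI67 1.32-fold higher. That list was called upward (camera adjusted p = 5.60e-07), with adjusted p = 0.184 with an estimated correlation. Cell cycle inhibitors were lower with E2 than with vehicle in 10 of 18 cases and higher in 4 (10 and 5 adjusted over the list alone). GADD45A was 1.87-fold and BTG1 1.54-fold lower, whereas CDKN1C, which encodes the inhibitor p57, rose 1.74-fold. This list was called downward (camera adjusted p = 0.0172), with adjusted p = 0.234 with an estimated correlation. Against baseline its mean was -0.05 in E2 arrays, not called (camera adjusted p = 0.222), and 0.13 in vehicle arrays.

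Estrogen-induced genes rose in 32 of 39 cases at 24 h and none fell (34 adjusted over the list alone), with GREB1 2.93-fold, MYBL1 2.74-fold and EGR3 3.10-fold higher (camera adjusted p = 3.70e-24, and 3.92e-06 with an estimated correlation). PGR was again not called, at 3.50 ± 0.02 (SD, n = 4) in E2 arrays. Of the 12 estrogen-repressed genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), TGFB3 by 2.17-fold and BIK, a gene that promotes cell death, by 1.86-fold, with BCL6 1.58-fold lower (camera adjusted p = 5.60e-07, and 0.00210 with an estimated correlation). Ribosome biogenesis genes rose in 27 of 31 cases and 1 fell (28 and 1 adjusted over the list alone), including UTP20 (1.53-fold) and NOLC1 (1.47-fold), with a camera adjusted p of 1.90e-10, and 0.00530 with an estimated correlation. Of 18 cholesterol synthesis genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), among them ACAT2 (1.54-fold), EBP (1.42-fold) and FDPS (1.26-fold), with a camera adjusted p of 1.76e-04, and 0.00828 with an estimated correlation.

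Several genes often used for normalization were higher with E2 than with vehicle at 24 h. Of 10 housekeeping genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone), HPRT1 by 1.43-fold, ACTB and PPIA by 1.13-fold and GAPDH by 1.09-fold (camera adjusted p = 0.0158, and 0.0390 with an estimated correlation). Against baseline this list was not called in E2 arrays (mean 0.05, camera adjusted p = 0.128), and its mean in vehicle arrays was -0.073. ESR1 rose by 0.32 on the log2 scale, WNT4 2.90-fold, SNAI1 1.42-fold, MYC 2.08-fold and CCND1 1.14-fold. CDH1 was 1.15-fold lower, the neural cadherin gene CDH2 2.19-fold lower and FGFR1 1.11-fold lower. FGFR3 rose 2.23-fold while FGFR4 was 1.63-fold lower. FZD7 rose 2.29-fold, KRT8 1.87-fold and TFAP2C 2.22-fold, and TWIST1 was 1.85-fold lower.

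The FGF list had 1 of 14 genes higher and 6 lower at 24 h (camera adjusted p = 0.203), the WNT list 5 of 32 higher and 7 lower (0.943), the adhesion list 8 of 24 higher and 10 lower (0.780) and the luminal factor list 4 of 19 higher and 8 lower (0.407). Immediate early genes were higher in 6 of 30 cases and lower in 10 (11 over the list alone; camera adjusted p = 0.785). Among cell type markers, 2 of 12 fibroblast genes were higher and SPARC was 1.77-fold lower (camera adjusted p = 0.780), 3 of 10 immune genes were lower (0.785), and 1 of 9 endothelial (0.895) and 1 of 7 basal genes (0.545) were higher. Adjusted over the list alone, 0 fibroblast genes were higher, 0 immune genes lower and 0 endothelial genes higher, with SPARC and the basal gene kept. The 3 prime minus 5 prime difference was 0.123 ± 0.013 (SD, n = 4) in E2 and 0.152 ± 0.021 in vehicle arrays at 24 h, with overlapping ranges. With 8 lists called, 5 of the 35 splits of these 8 arrays, the real one included, called as many, though mixed splits can retain part of the E2 effect. In 36 of the 2261 called genes with several probe sets, another probe set was called in the opposite direction.

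**Figure D3:**
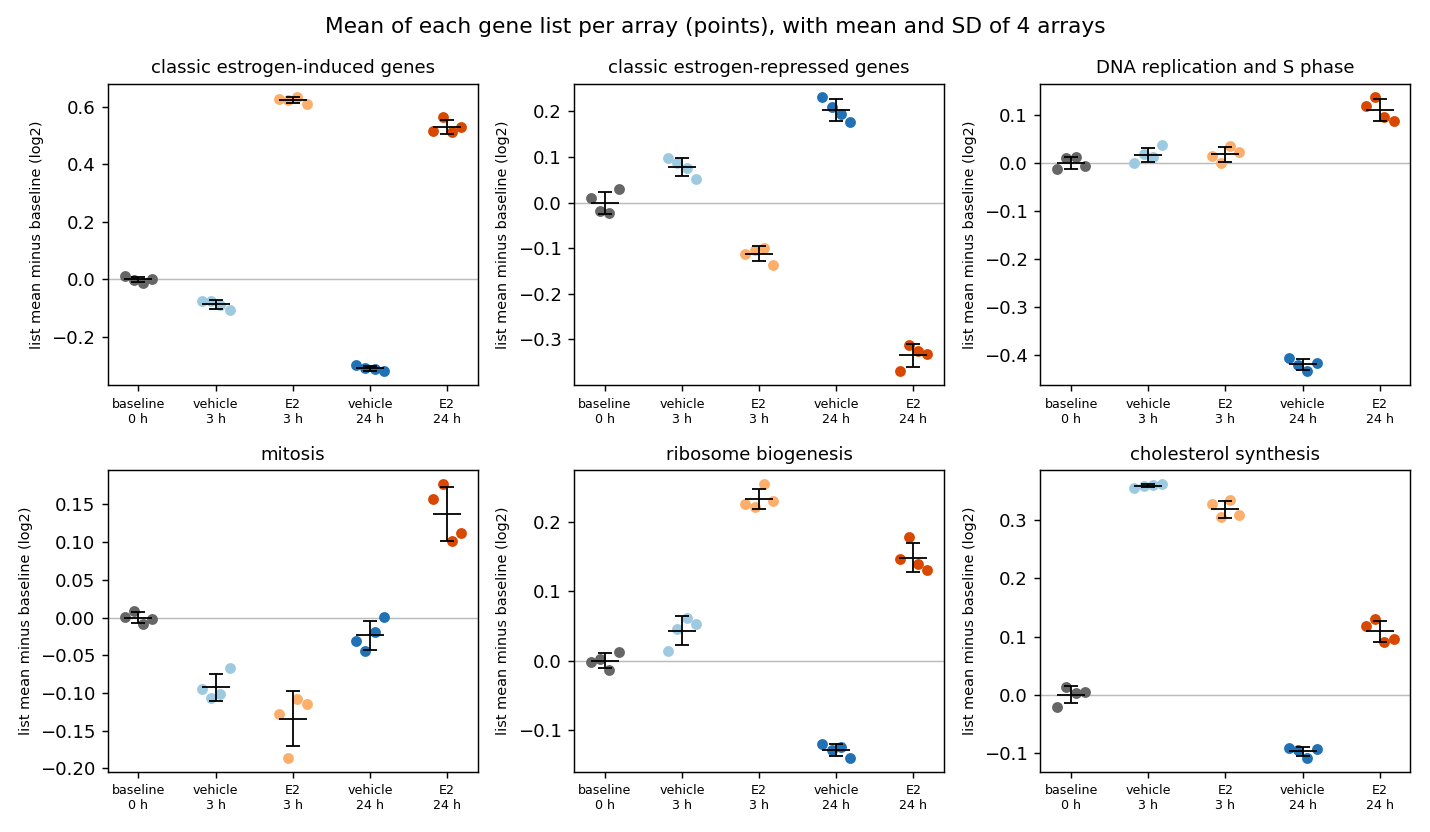
Mean of 6 gene lists in each array (points) minus the baseline mean, in log2 units, grouped by treatment and time; the black line and bars are the mean and SD of 4 arrays, and each panel has its own vertical scale. The DNA replication and S phase list averages 0.110 in E2 and -0.420 in vehicle arrays at 24 h, and the cholesterol synthesis list 0.359 in vehicle and 0.319 in E2 arrays at 3 h.

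The difference between times was tested as the E2 effect at 24 h minus that at 3 h. PDZK1 gained most, its effect being larger at 24 h by 3.32 ± 0.053 (SE) on the log2 scale (limma adjusted p = 3.59e-27). MGP (by 1.92), RGS5 (by 1.81), RGS7 (by 1.65) and CXCL13 (by 1.57), a chemokine gene, followed, and none of these last 4 was called at 3 h. The effect was more negative at 24 h for DEPP1 (-1.95) and MAP1B (-1.82), and for DDC (-1.78) and ATXN1 (-1.64), which were not called at 3 h. NR5A2 had a difference of -1.60, since its 3.66-fold rise at 3 h stood at 0.27 on the log2 scale at 24 h. CXCL12, a chemokine gene of the estrogen-induced list, was 1.33 higher on the log2 scale at 3 h and 0.00 at 24 h, a difference of -1.33 (limma adjusted p = 2.38e-20). Moves of the vehicle arrays between times enter these differences. PDZK1 lay at 8.42 to 8.52 in vehicle arrays at 3 h and at 6.39 to 6.51 at 24 h. In E2 arrays it lay at 9.39 to 9.51 and 10.7 to 10.8. DEPP1 lay at 7.4 to 7.5 and 9.2 to 9.3 in vehicle arrays at these times. Its E2 arrays lay at 6.5 to 7.3 and 6.6 to 6.8.

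By this test 3826 genes had effects that differed between times, 1922 upward and 1904 downward. The DNA replication and S phase list shifted upward in 40 of 42 genes (40 adjusted over the list alone; camera adjusted p = 1.84e-34, and 7.85e-05 with an estimated correlation), and cholesterol synthesis in 11 of 18 with 1 downward (11 and 1 adjusted over the list alone; 2.31e-06, and 0.00293 with an estimated correlation). Mitosis genes shifted upward in 28 of 41 cases (29 adjusted over the list alone; camera adjusted p = 2.81e-10), with adjusted p = 0.109 with an estimated correlation. Estrogen-repressed genes shifted downward in 7 of 12 cases with 1 upward (camera adjusted p = 1.26e-04, and 0.0138 with an estimated correlation), and housekeeping genes upward in 5 of 10 (0.00648, and 0.0265 with an estimated correlation). Immediate early genes shifted downward in 11 of 30 cases (12 over the list alone) with 3 upward, led by SPRY4 (-1.08) and MYC (-0.65), with a camera adjusted p of 0.0244, and adjusted p = 0.123 with an estimated correlation. Cell cycle inhibitors shifted downward in 8 of 18 cases (9 over the list alone) with 3 upward, FOXO1 by -0.87 and FOXO3 by -0.69 (camera adjusted p = 0.0468), with adjusted p = 0.298 with an estimated correlation. The estrogen-induced list had 14 of 39 genes upward and 7 downward (16 and 10 over the list alone) and was not called (camera adjusted p = 0.167). The upward shift of cholesterol synthesis was not a rise in E2 arrays, whose list mean relative to baseline was 0.319 at 3 h and 0.109 at 24 h. In vehicle arrays that mean was 0.359 and -0.097. The DNA replication and S phase mean was 0.018 and 0.110 in E2 arrays, and 0.017 and -0.420 in vehicle arrays. Most of that shift was thus a fall in vehicle arrays. For housekeeping genes the means were -0.010 and 0.050 in E2 arrays, and 0.004 and -0.073 in vehicle arrays. Mitosis genes moved mainly in E2 arrays, from -0.134 to 0.137, against -0.092 and -0.023 in vehicle arrays.

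Genes that responded at both times mostly kept their direction. Of the genes called at 3 h, 595 rose and 593 fell at both times, where 187 and 202 are the overlaps of independent lists, and 195 were called in opposite directions. SPRY4, an inhibitor of receptor tyrosine kinase signalling, was 0.35 higher at 3 h and -0.72 at 24 h on the log2 scale. HMGCS1 and INSIG1, of cholesterol synthesis, were 1.17-fold and 1.18-fold lower with E2 at 3 h, and their log2 changes at 24 h were 0.36 and 0.24. Across genes the log2 changes at both times correlated with Pearson's r of 0.508 and a Spearman coefficient of 0.317, where genes are not independent replicates. Of the 108 genes that rose at least 1.5-fold at 3 h, 101 were also called higher at 24 h.

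**Figure D4:**
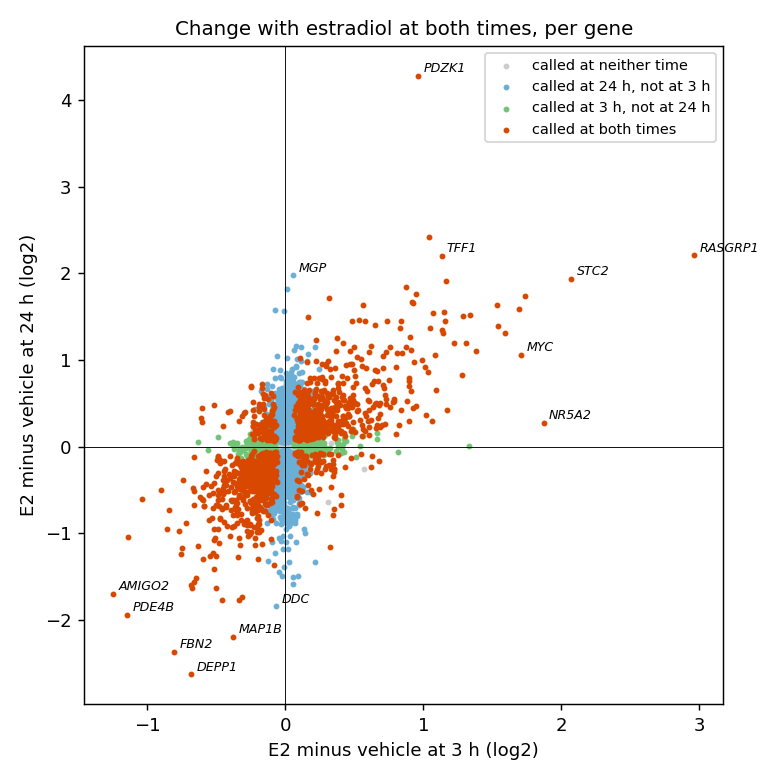
Log2 change with E2 against vehicle at 3 h (horizontal axis) and 24 h (vertical axis), with a point per gene, coloured by whether limma called the gene at either time, both or neither. Of the 11963 genes 1710 were called at 3 h and 5441 at 24 h; PDZK1 lies highest, at 4.28 at 24 h, and RASGRP1 farthest right, at 2.96 at 3 h.

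Vehicle-treated cells also moved away from the baseline. At 3 h HMGCS1, which encodes an early enzyme of cholesterol synthesis, was 2.43-fold higher in vehicle than at baseline (log2 change 1.28 ± 0.045 SE, n = 4 arrays per group, limma adjusted p = 1.95e-18). INSIG1, a sterol sensor gene, rose 2.24-fold, DUSP2 2.10-fold, RRAS2 2.01-fold and OTULINL 1.96-fold. MYC was 2.27-fold lower (limma adjusted p = 1.87e-21), DEPP1 2.02-fold, ARID5B 1.79-fold, FBN2 1.76-fold and MYB 1.56-fold lower. Of 18 cholesterol synthesis genes 12 rose and none fell (16 rose and 1 fell adjusted over the list alone), with MSMO1 at 1.74-fold and IDI1 at 1.66-fold (camera adjusted p = 1.29e-24, and 1.48e-06 with an estimated correlation).

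In the mitosis list 18 of 41 genes fell at 3 h (23 adjusted over the list alone), KIF20A by 1.23-fold, CENPA by 1.15-fold and AURKA by 1.13-fold (camera adjusted p = 9.42e-10), with adjusted p = 0.125 with an estimated correlation. Immediate early genes were higher in 13 of 30 cases, JUN by 0.32 on the log2 scale, and lower in 3 (14 and 4 over the list alone; camera adjusted p = 5.03e-04, and 0.0333 with an estimated correlation). Estrogen-induced genes fell in 12 of 39 cases and rose in 4 (14 and 5 adjusted over the list alone), STC2 by 1.30-fold (camera adjusted p = 7.23e-04, and 0.0333 with an estimated correlation). WNT genes were higher in 6 of 32 cases, FZD5 by 1.37-fold and WNT7B by 1.32-fold, and lower in 1 (6 and 2 over the list alone; camera adjusted p = 0.0228, and 0.0433 with an estimated correlation). Ribosome biogenesis genes rose in 4 of 31 cases (6 over the list alone; camera adjusted p = 0.0191), with adjusted p = 0.304 with an estimated correlation. Hypoxia and glycolysis genes rose in 3 of 22 cases, PFKFB3 by 1.42-fold (camera adjusted p = 0.0168), with adjusted p = 0.292 with an estimated correlation. CDKN1A, which encodes the inhibitor p21, rose 1.84-fold and ESR1 was 1.17-fold lower, a call lost with the mean of its probe sets (log2 change -0.04, adjusted p = 0.635). By limma 1656 genes were called, 822 higher and 834 lower, and 27 changed by at least 1.5-fold. The 3 prime minus 5 prime difference was 0.091 ± 0.010 (SD, n = 4) in these vehicle arrays and 0.149 ± 0.035 at baseline, with no overlap (highest 0.101 and lowest 0.117).

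By 24 h vehicle cells had lower S phase transcripts than at baseline. Of 42 DNA replication and S phase genes 41 fell and none rose (41 fell and 1 rose adjusted over the list alone), MCM10 by 1.67-fold, DTL by 1.66-fold, CDC6 by 1.58-fold and RRM2 by 1.42-fold. The list mean was -0.42 on the log2 scale (camera adjusted p = 1.15e-51, and 6.27e-06 with an estimated correlation). PDZK1 was 4.18-fold lower (limma adjusted p = 1.21e-25), MPPED2 2.25-fold, TFF1 2.05-fold, RLN2, a relaxin gene, 1.86-fold and RGS5 1.84-fold lower. DUSP2 rose 2.15-fold, TIMP3 2.07-fold, ID3 2.06-fold, ID1 1.98-fold and MAP1B 1.92-fold.

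Estrogen-induced genes fell in 27 of 39 cases and rose in 3 (27 and 3 adjusted over the list alone), STC2 by 1.81-fold (camera adjusted p = 2.33e-19, and 8.26e-06 with an estimated correlation), and 10 of 12 estrogen-repressed genes rose while 1 fell (8.87e-07, and 0.00227 with an estimated correlation). Ribosome biogenesis genes fell in 20 of 31 cases (camera adjusted p = 2.11e-08, and 0.0106 with an estimated correlation) and cholesterol synthesis genes in 7 of 18 (11 over the list alone; 1.91e-04, and 0.0106 with an estimated correlation). Cell cycle inhibitors rose in 10 of 18 cases, CDKN1A by 1.40-fold and GADD45A by 1.28-fold, and 1 fell (10 and 2 over the list alone; camera adjusted p = 2.31e-05, and 0.0286 with an estimated correlation). Immediate early genes were higher in 13 of 30 cases and lower in 2 (camera adjusted p = 0.00234, and 0.0286 with an estimated correlation). Adhesion genes were higher in 7 of 24 cases, CDH2 by 1.62-fold, and lower in 2 (8 and 2 over the list alone, camera adjusted p = 0.0136, and 0.0286 with an estimated correlation). Housekeeping genes were lower in 4 of 10 cases, HPRT1 by 1.22-fold (5 over the list alone; camera adjusted p = 0.00663, and 0.0241 with an estimated correlation). By limma 3065 genes were called, 1624 higher and 1441 lower, and 44 changed by at least 1.5-fold. The 3 prime minus 5 prime difference was 0.152 ± 0.021 in these arrays, close to the 0.149 ± 0.035 at baseline (SD, n = 4).

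Levels relative to baseline were read for MYC and the S phase list. MYC was 0.53 above baseline on the log2 scale in E2 arrays at 3 h and 0.39 at 24 h, against -1.18 and -0.66 in vehicle arrays. The DNA replication and S phase list mean was 0.110 ± 0.022 (SD, n = 4) in E2 arrays at 24 h and -0.420 ± 0.012 in vehicle arrays.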

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

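The tests of continued hormone deprivation, of the handling at treatment, of lists against the housekeeping list for scaling and of the cholesterol list in E2 arrays at 3 h were chosen after the results were seen, and the fit with the RNA quality covariate was added once the data had been examined. Whether chance alone could give such counts was examined by splitting the same arrays in other ways. For E2 against vehicle, 1 of 35 splits (the real one) gave as many genes as the 1710 at 3 h, the highest other split giving 0, and 1 of 35 as many as the 5441 at 24 h, the highest other giving 22. For vehicle against baseline, 1 of 35 splits gave 1656 genes at 3 h and 1 of 35 gave 3065 at 24 h, with 1 as the highest other in both. The 1188 genes called in the same direction at both times were reached in 1 of 100 draws, the real one, with 0 as the highest other. No other split or draw came near these counts. The share cannot go below 1 of 35, however, and mixing the groups adds the real effect to the spread, which lowers the counts of mixed splits. The splits alone therefore cannot exclude chance. For the number of lists called, 4 of 35 splits called at least the 5 lists of 3 h (highest other, 6) and 5 of 35 at least the 8 lists of 24 h (highest other, 9). Splits that swap a single pair of arrays retain part of the E2 effect, so they are no clean chance reference. These shares cannot decide whether chance gives such numbers of lists, and chance is not excluded for them.

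The effect of E2 differed between times in 3826 genes, which 1 of 100 draws reached, with 3823 as the highest other. That draw kept the 24 h groups whole and mixed the 3 h arrays, so it retains the effect at 24 h; the 94 draws that kept neither time whole gave 0. List means differed between times for DNA replication and S phase (0.529), cholesterol synthesis (0.247), mitosis (0.202) and housekeeping genes (0.137), all more positive at 24 h, and for estrogen-repressed genes (-0.348), immediate early genes (-0.146) and cell cycle inhibitors (-0.133). With an estimated correlation the calls of mitosis (adjusted p = 0.109), immediate early genes (0.123) and inhibitors (0.298) were lost. Single genes differed by 3.32 (PDZK1), 1.92 (MGP), 1.81 (RGS5), 1.65 (RGS7), 1.57 (CXCL13), 0.58 (HMGCS1) and 0.47 (INSIG1) on the log2 scale, and by -1.95 (DEPP1), -1.82 (MAP1B), -1.78 (DDC), -1.64 (ATXN1) and -1.60 (NR5A2). Of the 43 genes named for size or always in the E2 comparisons, 33 had effects that differed between times.

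A pattern to weigh is the fall of the S phase list below baseline in vehicle arrays at 24 h, by 0.420 ± 0.011 (SE) on the log2 scale. A shift shared by all genes of an array, which RMA largely removes, cancels between lists, and the change of this list minus that of the housekeeping list was -0.347, with a spread of 0.022. The housekeeping list was itself called lower in this comparison (mean -0.073, camera adjusted p = 0.00663), so it is no neutral reference. With the 3 prime minus 5 prime covariate the list difference was -0.420, and the covariate itself barely differed between these groups, so RNA integrity as measured here does not account for it. Continued hormone deprivation is a candidate explanation, since the estrogen-induced list stood at -0.310 from baseline in the same arrays and the estrogen-repressed list higher. Time in culture and cell density run with it, were not tested and stay open.

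The rise of the cholesterol synthesis list in vehicle arrays at 3 h was 0.359 ± 0.009 (SE). It was 0.355 when the change of the housekeeping list was subtracted, with a spread of 0.016. RMA makes the arrays nearly equal in distribution, and the median change over all genes was -0.007. The subtraction thus could not reveal a shift shared by all genes. It shows only that no such shift left in the deposited values accounts for the rise. The 3 prime minus 5 prime difference separates these vehicle arrays from baseline completely. In E2 arrays at 3 h, where the list was higher than baseline by 0.319 as well, it overlapped the baseline values (0.117 to 0.196) only in replicate C (0.183). The list stood at 0.334 from baseline in that array. The other E2 arrays lay at 0.113 to 0.114, below all baseline arrays. Resting on a single array, this overlap alone cannot decide whether RNA integrity was the whole cause. In E2 arrays at 24 h the 3 prime minus 5 prime difference was 0.123 ± 0.013 (SD, n = 4), against 0.131 ± 0.034 in E2 arrays at 3 h. Their list means from baseline were 0.109 ± 0.019 and 0.319 ± 0.014. These values, compared after the results were seen, argue against RNA integrity as measured here being the whole cause. A part in the rise is not excluded. A passing response to the handling at treatment, such as a change of medium, may be involved: at 24 h the list stood at -0.0972 from baseline. The labels do not say whether the medium was changed, and no fit could separate this from the passage of time.

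The number of genes called with E2 at 24 h was weighed against RNA integrity. With the covariate 5191 genes were called against 5441, and the ranges of the 3 prime minus 5 prime difference overlapped, so that measure does not account for the number of calls.

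Among 299 groups of 4 arrays tested for a lone array, 14 had a gap beyond the critical value of Dixon's test, where chance gives about 15. For genes the share of the range was 0.879 for FLRT3 (vehicle 3 h, replicate B above), 0.865 for JAK2 (E2 3 h, C below), 0.852 for MYC (E2 3 h, B below), 0.889 for PGR (E2 3 h, D below), 0.949 for RND1 (vehicle 3 h, A below), 0.899 for MGP (E2 24 h, A above), 0.842 for RGS5 (baseline, A above) and 0.948 for INSIG1 (vehicle 3 h, A above). For list means it was 0.836 for adhesion and 0.845 for luminal factors (both E2 24 h, B above), 0.874 for hypoxia and glycolysis (E2 3 h, C above), 0.893 for oxidative phosphorylation (E2 3 h, B below) and 0.864 for basal markers (E2 3 h, B above). For interferon-stimulated genes it was 0.933, replicate B of vehicle at 24 h lying at 7.02 and the others at 6.82 to 6.83.

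Probe sets with no gene symbol or several, which the gene comparisons leave out, were tested separately with limma. Of 3151, 220 were called at 3 h (123 higher with E2) and 926 at 24 h (439 higher). Among those with no symbol, the largest rise was 2.62-fold at 3 h and 2.83-fold at 24 h, and the largest fall 1.49-fold and 4.64-fold.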

How the results depend on the processing

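The fit with the RNA quality covariate was added after seeing the data; the other alternatives were planned. Testing all probe sets, which are more numerous, called 2578 at 3 h, 9045 at 24 h, 6074 for the difference of effects and 4744 for vehicle at 24 h against baseline. A minimum of 1.5-fold left 142, 508, 353, 27 (vehicle 3 h), 44 (vehicle 24 h) and 88 (both times), since most called changes are small. At a threshold of 0.01 vehicle at 3 h against baseline had 1062 genes. Against baseline arrays as control, 2844 genes were called with E2 at 3 h and 4291 at 24 h, and the cause was not tested. With an estimated correlation 3 lists were called at 3 h, and fry, which asks only whether a list moves, called 10 at 3 h and 19 at 24 h. The covariate gave 1540 genes at 3 h and 5191 at 24 h. At 3 h its values did not overlap between E2 and vehicle arrays, so that fit cannot separate RNA integrity from E2. Other settings kept each count within 1.5 times, and no other scaling moved the split of higher and lower calls by over 10 points.

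Leaving out single arrays gave 1488 to 1552 genes for E2 at 3 h, 5177 to 5336 at 24 h, 3611 to 3812 for the difference, 1405 to 1504 and 2695 to 2946 for vehicle at 3 and 24 h, 1052 to 1214 for both times, and 4 to 5 and 8 to 9 lists. With the letter as a block the counts were 1612, 5324, 3719, 1566 and 2926 genes, 1127 at both times, and 5 and 8 lists. Deviations of arrays with the same letter correlated at -0.20 to 0.12, and not every array was closest to its own letter, so the letters were not taken as pairs.

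Of 1254 values of the named genes under alternatives, 1235 kept their call, and their direction where called, 9 lost and 9 gained a call, and 1 called value reversed. A change of sign in a value called in neither setting was counted as kept. The reversed value was ESR1 at 3 h, at -0.0257 on the log2 scale with the mean of its probe sets, which disagree. Cyclic loess or quantile scaling turned the sign of the means of 4 uncalled lists, apoptosis and fibroblast markers at 3 h, interferon-stimulated genes at 24 h and endothelial markers in the difference.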

Other observations

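The list tests of this part were planned, and a few genes beyond the naming rule were picked after their values were seen. Nutrient and metabolic genes responded to E2 in ways their lists as a whole did not. SLC7A5, a leucine transporter gene, rose 2.53-fold at 3 h and 2.87-fold at 24 h, while the cystine transporter gene SLC7A11 was 1.29-fold and 1.89-fold lower and SLC38A2 1.27-fold and 1.39-fold lower. The list of amino acid transport and tRNA synthetase genes had 8 of 23 higher and 3 lower at 3 h (10 and 4 over the list alone; camera adjusted p = 0.0796) and 9 higher and 6 lower at 24 h (10 and 6; 0.407). PFKFB3, which promotes glycolysis, rose 1.68-fold and 1.71-fold. The glucose transporter gene SLC2A1 rose 1.61-fold and VEGFA 1.28-fold at 3 h. At 24 h ENO1 rose 1.30-fold, while VEGFA was 1.22-fold and HK2 1.47-fold lower. Hypoxia and glycolysis genes were higher in 4 of 22 cases at 3 h (5 over the list alone; camera adjusted p = 0.0796) and 10 at 24 h (11; 0.0684), and lower in 2 and 6. Oxidative phosphorylation genes had 0 of 28 called at 3 h (0.762) and 11 higher and 3 lower at 24 h (0.203), with CYCS 1.19-fold higher.

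Genes of cell death, protein folding and steroid response also changed singly. PMAIP1, which encodes the death-promoting protein NOXA, rose 1.89-fold at 3 h and 3.18-fold at 24 h, and BID rose 1.72-fold at 24 h. BCL2, which opposes cell death, rose 1.19-fold at 3 h. The apoptosis list had 3 of 19 higher and 5 lower at 3 h (3 and 8 over the list alone; camera adjusted p = 0.486) and 3 higher and 6 lower at 24 h (4 and 6; 0.780). Unfolded protein response genes were higher in 3 of 21 cases and lower in 3 at 3 h (3 and 4 over the list alone; 0.964), and higher in 12 and lower in 7 at 24 h (0.128), with SDF2L1 1.52-fold higher and HERPUD1 1.43-fold lower. SGK1 rose 1.63-fold and 1.64-fold and PMEPA1 1.86-fold at 3 h, and KLF9 was 2.26-fold lower at 24 h. The androgen and glucocorticoid response list had 2 of 13 higher at 3 h (0.189) and 3 higher and 5 lower at 24 h (0.780). Interferon-stimulated genes were higher in 3 of 33 cases at 3 h (1 over the list alone; 0.102) and in 7 at 24 h, with 4 lower (6 and 3 over the list alone; 0.806), where replicate B of the vehicle group at 24 h stood above the other 3 in the list mean.

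For lists not called with E2 the mean and the median differed in sign in several cases. This was so at 3 h for S phase, unfolded protein response, WNT, luminal factor, steroid response, fibroblast and immune lists, and at 24 h for immediate early, WNT, apoptosis, interferon, steroid response and endothelial lists. The direction of those list means is therefore not given.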
